A study of Homo sapiens with 58 samples.

How the data were processed

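Biopsies of duodenal mucosa from 37 people with functional dyspepsia and 21 healthy controls were measured by paired-end sequencing of total RNA, with libraries made by a stranded total RNA kit, per the labels' protocols. Reads were aligned with TopHat to hg38 and counted with featureCounts, per the submitters' processing notes, and the versions are not given in the sources used here. The deposited table holds RPKM for all 58 libraries, per the file headers. It holds gene counts for the 21 control libraries, per the file headers. Whether counting used strand is not given in the sources used here, so overlapping and antisense genes are uncertain, as are paralogs and pseudogenes.

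The table has 64253 genes. Gene lengths behind the RPKM were derived from the control libraries, and whole reads were then recovered for every library: at least 99.9881% of values per library were whole within 0.05 reads, and 100% of nonzero control values equalled the deposited count. The lengths came from these same control counts, so that match is no independent check. For functional dyspepsia libraries the share of whole values is the only check. Of the mapped reads that the RPKM imply, 56.5% in functional dyspepsia and 55.2% in controls were assigned to genes.

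Groups came from the disease label. The design fixed before the data were examined named edgeR with TMM factors for counts and limma on log2 values for another unit, with the gene lists, the rule for named genes and the alternative settings fixed at the same time. Because functional dyspepsia libraries carry RPKM, limma 3.58.1 with an intensity trend was used on log2(RPKM × scale factor + 0.1), with Benjamini-Hochberg adjustment. Fold changes on this scale understate the change of low genes. Genes with an RPKM of at least 0.1 in at least 21 libraries were tested. TMM scaling was kept for RPKM only after the shift of the deposited values between groups had been seen, so results with the values as deposited stand beside it. The mean log2 scale factor was 0.14 in controls and -0.08 in functional dyspepsia. Sex-linked marker genes were left out because the donors are people. The labels give no age, sex or batch, so the tests adjusted for none of these, and the groups may differ in them.

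The 40 gene lists were tested by camera with a preset correlation of 0.01 and by a 2-sided permutation test of the mean log2 value per library (100000 resamples, adjusted over the lists); the smallest p it can give is 1e-05. Camera was run on log2 RPKM in place of the planned voom values. Where several rows share a symbol, the row whose identifier carries that symbol was used, a choice made after first results had been seen. Some symbols in the table belong to another gene in GENCODE 29 by their identifier, and such rows are left out of the text or named as such.

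Genes were named by a fixed rule. It takes the 10 largest log2 fold changes in each direction among calls with at least 1 log2 CPM and 75% of functional dyspepsia libraries on the same side of the control median, up to 4 members per list, and 20 barrier and immune genes, of which PRG2 and DUOX2 were not tested. The part for the largest changes was repeated among protein-coding genes after the values were seen. Small RNAs, pseudogenes and mitochondrial copies among the largest changes are summarised, and 1 gene that the rule named is not reported here.

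On counts simulated from these libraries for the comparison of functional dyspepsia with controls (31826 genes, 200 changed), limma recovered 52% of genes changed 1.25-fold, 82% at 1.5-fold, 96% at a fold of 2 and 100% at a fold of 4, and called 4 unchanged genes. Simulated genes were independent, unlike real ones. The changed genes were drawn only from those above a minimum mean of reads, and the groups were given no other difference in composition. These figures therefore do not cover low genes or the choice of scaling. Alternatives used edgeR 4.0.16, DESeq2 1.42.0 and sva 3.50.0 on recovered reads, in R 4.3.3. The edgeR quasi-likelihood test called 1704 genes higher and 2959 lower among 32119. Gene types came from GENCODE 29, in which 56591 of the identifiers were found.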

Results

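Total RNA was sequenced from duodenal mucosal biopsies of 37 people with functional dyspepsia, a disorder of upper abdominal symptoms, and 21 healthy controls, 1 library per person. The series was designed around the duodenal barrier, and the comparison asks how mucosal gene expression differs between the groups. Reads assigned to genes came to 78.3 ± 17.3 M per library (SD, n = 37, range 48.3 to 120.03) in functional dyspepsia and 118 ± 31.7 M (SD, n = 21, range 49.2 to 198) in controls, a difference past a 2-sided permutation test (adjusted p = 2e-05). The number of genes with a read did not differ detectably (41871 ± 1161 against 41901 ± 1163, adjusted p = 0.925). The control libraries are marked as also belonging to another series, so group and deposit cannot be told apart in this comparison. The most similar pair of libraries differed 9.51 times more than Poisson sampling would give, so no library was counted as a duplicate of another.

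In functional dyspepsia the mitochondrially encoded transcripts, the inducible nitric oxide synthase NOS2, the iron exporter SLC40A1 and the quinone reductase NQO1 were lower, and the Paneth cell defensins DEFA5 and DEFA6 were higher. NOS2 (ENSG00000007171, chromosome 17, 27756766 to 27800499 on hg38) fell by 1.41 on the log2 scale (SE 0.26, adjusted p = 0.000111), with 35 of 37 functional dyspepsia libraries below the control median. DEFA6 (ENSG00000164822, chromosome 8, 6924693 to 6926076) rose by 0.95 (SE 0.25, adjusted p = 0.0068), with 29 of 37 libraries above it. These differences kept their direction and passed the test with and without rescaling of the libraries. Without rescaling the median gene was higher by 0.20 on the log2 scale. That comparison is therefore a check on the lower genes and not on the defensins, which it favours. With the total of assigned reads as a covariate SLC40A1, NQO1 and DEFA5 lost their calls. DEFA5 also lost its call with the mean of brush border genes, and DEFA5 and DEFA6 with the share of mitochondrial reads. That share was 1.03% in functional dyspepsia and 1.57% in controls (permutation test, adjusted p = 2e-05). As a covariate it therefore removes part of the group difference. Most differences in junction and absorptive genes were smaller and depended on that rescaling as well as on covariates for depth or absorptive cell content.

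Across 31826 genes tested by limma on log2 TMM-scaled RPKM, 2045 were higher and 2738 lower in functional dyspepsia at an FDR of 0.05, so 42.8% of calls were higher. With the RPKM as deposited, 13776 were higher and 370 lower, 97.4% of calls higher, because the median gene then moved by 0.20 on the log2 scale, against 0.02 after scaling. Of the 4783 calls, 2414 were made in the same direction with the values as deposited. With upper-quartile scaling 2847 were higher and 2192 lower, 56.5% of calls higher. Fold changes were small, with a median size of 0.30 among the calls, and 46 higher and 44 lower genes differed by a fold of more than 2 on the fitted scale. Among protein-coding genes 549 were higher and 2093 lower, while 133 of 544 small nucleolar RNA genes were higher and 9 lower. That balance of protein-coding genes turned with the values as deposited, to 6573 higher and 175 lower, and 288 small nucleolar RNA genes were then higher and 4 lower.

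Among the largest changes, the alkaline phosphatase gene ALPP fell by 1.75 (SE 0.49, adjusted p = 0.0111), with 35 of 37 functional dyspepsia libraries below the control median. It can share reads with its paralogs and overlaps an antisense gene. Its call was lost with the brush border score (-1.09, adjusted p = 0.165), the library total (-0.84, adjusted p = 0.439) or the share of small nucleolar RNA reads (-1.44, adjusted p = 0.0862) as a covariate. The vesicular glutamate transporter gene SLC17A8 fell by 1.10 (SE 0.21, adjusted p = 0.000184), with 35 of 37 libraries below the control median. SPHAR, which overlaps an exon of RAB4A, fell by 1.02 (SE 0.12, adjusted p = 2.77e-08), with 37 of 37 below it. The metallothionein gene MT2A fell by 0.93 (SE 0.24, adjusted p = 0.00524), with 30 of 37 below it. Its call was lost with the mitochondrial share as a covariate (-0.70, adjusted p = 0.0807). NLRP2, of the NOD-like receptor family, rose by 0.94 (SE 0.25, adjusted p = 0.00689), with 31 of 37 above the control median. Its call was lost with title prefixes weighted equally (0.72, adjusted p = 0.0746). All 5 passed with the values as deposited (adjusted p from 1.28e-05 to 0.0162). That setting moves genes upward, so it is no check on the rise of NLRP2. The antimicrobial lectin gene REG3A rose by 0.59 (adjusted p = 0.0148). Its call was lost with the brush border score (0.44, adjusted p = 0.124), the mitochondrial share (0.38, adjusted p = 0.193) or the library total (0.64, adjusted p = 0.0612). METTL12 rose by 0.75 and has a small nucleolar RNA gene, SNORA57, within its exons, which did not itself pass (0.33, adjusted p = 0.0533). Of small RNAs, 2 genes named ACEA_U3 rose by 1.90 and 1.12, RNY1 rose by 0.76 and U1 rose by 0.85. The second ACEA_U3 gene varied widely in functional dyspepsia (144 ± 792 scaled RPKM, SD, against 7.63 ± 3.33 in controls), and its log2 fold change by edgeR was 4.24. By edgeR U1 did not pass (adjusted p = 0.0542). The pseudogene PTMAP5 fell by 1.15 and the nuclear copies of mitochondrial genes MTATP6P1 and MTND1P23 fell by 1.36 and fell by 1.05. MTND1P23 lost its call with the mitochondrial share (-0.20, adjusted p = 0.276).

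The 13 protein-coding genes of the mitochondrial genome were lower as a group. Of these, 12 fell over all genes tested and 13 adjusted over the list alone, and the list score was lower by permutation (difference -0.78, adjusted p = 4e-04). MT-ATP8, an ATP synthase subunit, fell by 1.38 (SE 0.18, adjusted p = 1.71e-07), MT-CO2 fell by 0.90 (SE 0.12) and MT-CO3 fell by 0.68 (SE 0.11). With the values as deposited 10 of the 13 still fell and the score difference was -0.56 (adjusted p = 6e-04). The mitochondrial ribosomal RNA MT-RNR1 fell by 1.67 and RNA28S5, a fragment annotated as 28S ribosomal RNA, fell by 4.31. Both vary widely between controls (1421 ± 2202 and 6567 ± 9570 scaled RPKM, SD, n = 21), and the share of reads on mitochondrial ribosomal RNA was 0.368% in functional dyspepsia and 1.00% in controls. Nuclear-encoded respiratory chain genes had 6 of 59 members lower over all genes and 4 adjusted over the list alone, and their score did not pass (difference -0.12, adjusted p = 0.265). The direction turned with the values as deposited, with 5 members higher and a score difference of 0.11 (adjusted p = 0.358), and 3 were lower on the scaled values without control replicate 8 or 13. Other settings gave counts in both directions, 45 lower with the mitochondrial share as a covariate, 19 with surrogate variables and 13 with sample weights, and 2 higher with the brush border score or the library total.

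Among tight junction genes 8 of 34 were lower and 1 higher over all genes, and 8 lower and 2 higher adjusted over the list alone. The call of the higher gene was lost without control replicate 1, 2, 4, 6, 8, 12, 16, 18 or 21 or functional dyspepsia replicate 3, 5, 25 or 33, and 2 were higher without control replicate 5 or 9 or functional dyspepsia replicate 11. The score was lower in functional dyspepsia (difference -0.11, adjusted p = 0.0144), but with the values as deposited its difference was 0.10 in the other direction (adjusted p = 0.109) and 10 members were higher. By limma 2 members were lower with the brush border score as a covariate, 0 with the library total, where 6 were lower at an unadjusted p under 0.05, and 15 with surrogate variables. Without control replicate 8, the highest of the controls, the difference was -0.08 (adjusted p = 0.0447). OCLN, which encodes occludin, fell by 0.32 (SE 0.08, adjusted p = 0.00264) and the scaffold gene TJP1 fell by 0.22 (SE 0.06, adjusted p = 0.0116). With the values as deposited neither OCLN (adjusted p = 0.336) nor TJP1 (adjusted p = 0.991) passed. CLDN12 fell by 0.38 and PRKCI fell by 0.26, and they lost their calls with the values as deposited (adjusted p = 0.128 and 0.716). The claudins CLDN1, CLDN2, CLDN3, CLDN4, CLDN7 and CLDN15 did not pass, with log2 fold changes from -0.33 in CLDN4 (adjusted p = 0.116) to -0.05 in CLDN3 (adjusted p = 0.807). F11R, a junctional adhesion molecule gene, had a log2 fold change of -0.18 (adjusted p = 0.0984).

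Adherens junction and desmosome genes had 10 of 19 members lower, and 12 adjusted over the list alone. Their score differed by -0.21 (adjusted p = 0.000533), and by 0.01 with the values as deposited (adjusted p = 0.888), where 2 were higher and 1 lower. The count of 10 was 5 with the brush border score as a covariate, 1 with the library total and 15 with surrogate variables. CDH1, the gene of E-cadherin, fell by 0.26 (adjusted p = 0.00503), EPCAM fell by 0.39 (adjusted p = 0.000989) and PERP fell by 0.51 (adjusted p = 0.000482). With the values as deposited PERP stayed lower (-0.29, adjusted p = 0.0317), while CDH1 and EPCAM lost their calls (adjusted p = 0.716 and 0.122). Brush border genes had 10 of 29 members lower, and 11 adjusted over the list alone, with a score difference of -0.25 (adjusted p = 0.00735) that was -0.03 with the values as deposited (adjusted p = 0.818), where 1 was higher and 1 lower. By limma 0 were lower with the library total as a covariate, where 5 were lower at an unadjusted p under 0.05, and 20 with surrogate variables. SLC40A1 fell by 0.95 (SE 0.23, adjusted p = 0.00263), from 205 ± 115 scaled RPKM in controls to 116 ± 85.5. Its call was lost with the library total as a covariate (-0.81, adjusted p = 0.0754). Transmembrane mucins had 3 of 7 members lower and 5 adjusted over the list alone, with 5 lower over all genes without control replicate 17, and a score difference of -0.36 (adjusted p = 0.0015) that was -0.18 with the values as deposited (adjusted p = 0.0619). With the library total as a covariate 1 transmembrane mucin gene was lower, and by limma 0 with the brush border score or the mitochondrial share, where 4 and 1 were lower at an unadjusted p under 0.05. MUC17 fell by 0.60 and MUC3A fell by 0.69, and both passed with the values as deposited (adjusted p = 0.0324 and 0.0354). Of 15 secreted mucus genes 0 passed by limma, over all genes or adjusted over the list alone, and 0 by edgeR, with 2 at an unadjusted p under 0.05, and MUC2 had a log2 fold change of -0.13 (adjusted p = 0.644). With the values as deposited 2 mucus genes were higher, and 1 was lower with surrogate variables or with sample weights.

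Ion transport genes had 4 of 27 members lower, and 8 adjusted over the list alone, with 7 higher and 1 lower with the values as deposited, 4 higher and 4 lower with the brush border score as a covariate, 1 higher and 2 lower with the library total, and 3 higher and 10 lower with surrogate variables. Their score differed by -0.12 (adjusted p = 0.0318), and by 0.10, in the other direction, with the values as deposited (adjusted p = 0.0716). The call was kept in 54 of 58 fits that left out 1 library, and was lost without control replicate 4, 6, 7 or 8 (adjusted p = 0.0523, 0.0625, 0.0567 and 0.0842). The bicarbonate cotransporter gene SLC4A7 fell by 0.54 (adjusted p = 0.00031) and passed with the values as deposited (adjusted p = 0.0135), while SLC4A4 fell by 0.35 and lost its call (adjusted p = 0.155). CFTR and SLC26A3 did not pass in limma (log2 fold changes -0.13 and -0.52, adjusted p = 0.215 and 0.074), and by edgeR SLC26A3 passed (adjusted p = 0.0114). Bile acid genes had 5 of 11 members lower, and 7 adjusted over the list alone, with a score difference of -0.25 (adjusted p = 0.0028) that was -0.04 with the values as deposited (adjusted p = 0.753). Over all genes 3 were lower without control replicate 1, 6, 10, 13, 16, 17 or 21 or functional dyspepsia replicate 2, 7, 13, 24, 31 or 33. By limma 0 were lower with the brush border score or the library total as a covariate, where 2 and 1 were lower at an unadjusted p under 0.05, and the values as deposited gave 1 higher and 1 lower.

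Smooth muscle genes differed in the direction opposite to the junction and brush border lists. Of 10, 6 were higher and 8 adjusted over the list alone, with a score difference of 0.40 (adjusted p = 0.022), and TAGLN rose by 0.51 (adjusted p = 0.00109). With the values as deposited 9 were higher and the score difference was 0.60 (adjusted p = 0.00287). That setting moves list scores up in general, so it is no check on lists that were higher. The count of 6 was 2 without control replicate 8, 3 without control replicate 1, 2, 6 or 16, 3 without the 3 most distant libraries, with no filter or with the mitochondrial share as a covariate, 2 with title prefixes weighted equally, and 1 with the brush border score or the library total as a covariate. Paneth cell genes had 5 of 7 members higher, and 5 adjusted over the list alone, with a score difference of 0.50 (adjusted p = 0.00735) that was 0.72 with the values as deposited (adjusted p = 0.000533). DEFA5 rose by 0.75 (SE 0.23, adjusted p = 0.0184) and the lectin gene ITLN2 rose by 0.67 (adjusted p = 0.0238). The row named PRSS3P2, whose identifier belongs to the trypsinogen gene PRSS2, rose by 0.69 and can share reads with its paralogs. Without control replicate 1 the count of Paneth genes was 3 and ITLN2 lost its call (adjusted p = 0.0501). By limma 0 of the 7 were higher with the mitochondrial share as a covariate, where 2 were higher and 1 lower at an unadjusted p under 0.05. There the log2 fold changes were 0.47 in DEFA5 (adjusted p = 0.226), 0.57 in DEFA6 (adjusted p = 0.178), 0.49 in ITLN2 (adjusted p = 0.176) and 0.51 in PRSS3P2 (adjusted p = 0.154). The count was 1 with the brush border score and 2 with the library total or without the 3 most distant libraries, and DEFA5 lost its call in each, with log2 fold changes of 0.68, 0.86 and 0.65 (adjusted p = 0.0721, 0.0589 and 0.0551). ITLN2 lost its call with the brush border score (0.67, adjusted p = 0.0555) and without the 3 most distant libraries (0.57, adjusted p = 0.0649). PRSS3P2 lost its call with the brush border score (0.59, adjusted p = 0.093) and the library total (0.64, adjusted p = 0.142). With the share of small nucleolar RNA reads as a covariate DEFA5 (0.62, adjusted p = 0.115) and DEFA6 (0.77, adjusted p = 0.0685) lost their calls. So did ITLN2 (0.54, adjusted p = 0.142) and PRSS3P2 (0.56, adjusted p = 0.12). Ribosomal protein genes had 19 of 69 members higher and 25 adjusted over the list alone, and 20 of the 69 hold a small RNA gene within an annotated exon. Of those 20, 8 were higher (median log2 fold change 0.19), and of the 49 without one 11 were (median 0.14). The count of 19 was 67 with the values as deposited, 34 with upper-quartile scaling and 32 with surrogate variables, and the mitochondrial share as a covariate gave 1 higher and 3 lower. Their score differed by 0.16 (adjusted p = 0.0401), and by 0.39 with the values as deposited (adjusted p = 0.000533), and the call was kept in 35 of 58 fits that left out 1 library. It was lost without control replicate 1, 4, 6, 7, 9, 10, 12, 14, 18 or 20 or functional dyspepsia replicate 3, 4, 12, 14, 15, 19, 20, 21, 22, 23, 33, 35 or 36 (adjusted p from 0.0508 to 0.0853).

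Oxidative stress and hypoxia genes had 10 of 18 members lower, and 10 adjusted over the list alone, with a score difference of -0.37 (adjusted p = 0.000533) that was -0.15 with the values as deposited (adjusted p = 0.161), where 2 were higher and 5 lower. The count of 10 was 4 with the brush border score and 3 with the library total as a covariate, where NQO1 lost its call (-0.63, adjusted p = 0.106). NQO1 fell by 0.93 (SE 0.20), GCLC fell by 0.50 and GCLM fell by 0.60, and the hydroxylase gene EGLN3 fell by 0.82. All 4 passed with the values as deposited as well (adjusted p from 0.00393 to 0.0261). Interferon-induced genes had 6 of 30 members lower, and 6 adjusted over the list alone, with a score difference of -0.26 (adjusted p = 0.00735) that was -0.06 with the values as deposited (adjusted p = 0.704), where 2 were lower. The count of 6 was 1 with the brush border score or the library total as a covariate, 15 with surrogate variables and 10 by edgeR. RSAD2 fell by 0.94 (adjusted p = 0.000135) and OASL fell by 0.90 (adjusted p = 0.0109), and both passed with the values as deposited. Immediate-early genes, which respond to tissue handling, had 5 of 18 members lower and 8 adjusted over the list alone (score difference -0.29, adjusted p = 0.0293), led by JUND, which fell by 0.70. That list call was lost with the values as deposited (adjusted p = 0.546) and without control replicate 1, 7, 8 or 14 (adjusted p = 0.0707, 0.0567, 0.0627 and 0.0508), and 3 members were lower without control replicate 1, 6, 8 or 20 or functional dyspepsia replicate 13. With the brush border score 3 were lower, with the library total 2 and with the mitochondrial share 8. Heat shock genes had 4 of 12 members lower and 6 adjusted over the list alone, with a score difference of -0.20 (adjusted p = 0.0272) that was 0.01 with the values as deposited (adjusted p = 0.909) and was lost without control replicate 7, 8 or 17 (adjusted p = 0.051, 0.0627 and 0.0531). The count of 4 was 1 without control replicate 3, 7, 8, 13 or 19 or functional dyspepsia replicate 24 or 31, and 2 without control replicate 1 or 17 or functional dyspepsia replicate 2, 7, 25 or 33, 2 with upper-quartile scaling, 1 with the brush border score or the library total as a covariate, and 7 with surrogate variables. HSPB1 fell by 0.65 (adjusted p = 3.27e-05) and passed with the values as deposited (adjusted p = 0.00132). Circadian clock genes had 1 of 15 members lower and 5 adjusted over the list alone. Their score differed by -0.17 (adjusted p = 0.0272), and by 0.04 with the values as deposited (adjusted p = 0.704), where 3 were higher and 1 lower. The score call was kept in 58 of 58 fits that left out 1 library (adjusted p up to 0.0491).

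Mast cell and eosinophil lists did not differ detectably after scaling. The mast cell score differed by 0.05 (adjusted p = 0.644), and by 0.24 with the values as deposited (adjusted p = 0.0518), where 5 of 15 genes were higher. With scaling 1 of 15 members was lower both over all genes and adjusted over the list alone. That member was the transporter gene SLC18A2, which fell by 0.34 (adjusted p = 0.000806), a call lost with the values as deposited (adjusted p = 0.289). TPSAB1 and CPA3 had log2 fold changes of -0.05 (adjusted p = 0.875) and 0.17 (adjusted p = 0.466). Only 7 of the 15 eosinophil genes were tested, and CCR3, IL5RA, PRG2, PRG3, EPX, RNASE2, RNASE3 and CCL26 were not, so most of these markers could not be compared. Of the 7, 0 passed in limma and 0 in edgeR, with 1 at an unadjusted p under 0.05. The score differed by 0.09 (adjusted p = 0.422), against 0.27 with the values as deposited (adjusted p = 0.0375). CLC, at a low average of 0.32 log2 CPM, had a log2 fold change of 0.02 (adjusted p = 0.971). Of 24 T-cell genes 0 passed in limma and 2 were lower by edgeR, with 3 at an unadjusted p under 0.05 in limma. With the values as deposited 3 were higher and 0 lower. Cytokine and inflammation genes had 1 of 20 members higher and 3 lower, and as many adjusted over the list alone, with a score difference of -0.16 (adjusted p = 0.036) that was 0.02 with the values as deposited (adjusted p = 0.818) and was lost without control replicate 1, 4, 7, 8, 9, 17 or 19 or functional dyspepsia replicate 28 (adjusted p from 0.0505 to 0.0683). IL1B and TNF had log2 fold changes of -0.56 (adjusted p = 0.0897) and -0.16 (adjusted p = 0.267) by limma, and by edgeR IL1B passed (adjusted p = 0.00485). Both were low. IL1B was 0.25 ± 0.33 scaled RPKM in functional dyspepsia and 0.66 ± 1.54 in controls (SD, n = 37 and 21), and TNF means were 0.36 and 0.40. Of the 32 list members 20 were tested, and IL6, CXCL8, IL10 and IL17A were among those not tested.

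Camera with a preset correlation called 8 lists higher and 16 lower. With an estimated correlation it called none, the lowest being adjusted p = 0.178 with an estimated correlation, and relabelled libraries gave a median of 13 called lists with the preset, so list statements here rest on the permutation of library scores.

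**Figure D1:**
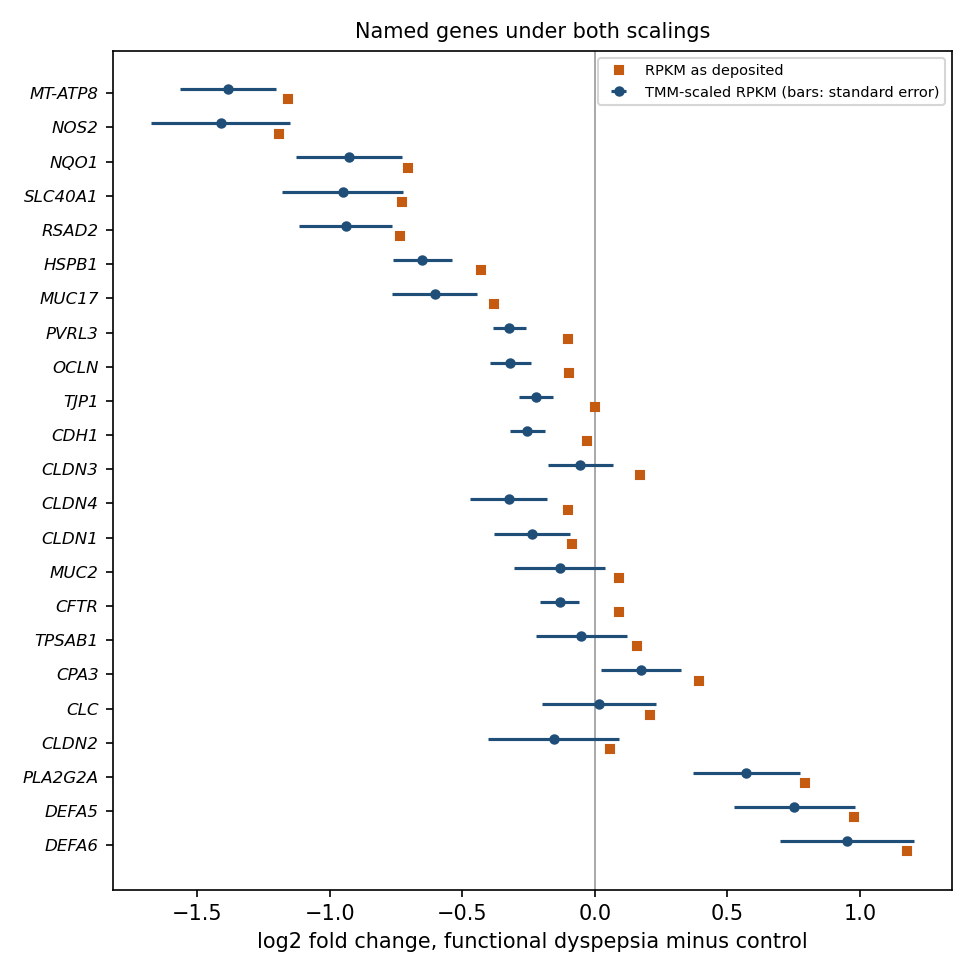
Log2 fold changes of named genes, functional dyspepsia minus control, on the x axis, with circles for TMM-scaled RPKM (bars are standard errors) and squares for RPKM as deposited. The squares lie to the right of the circles, so that OCLN moves from -0.32 to -0.10 while DEFA6 stays higher and NOS2 stays lower.

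**Figure D2:**
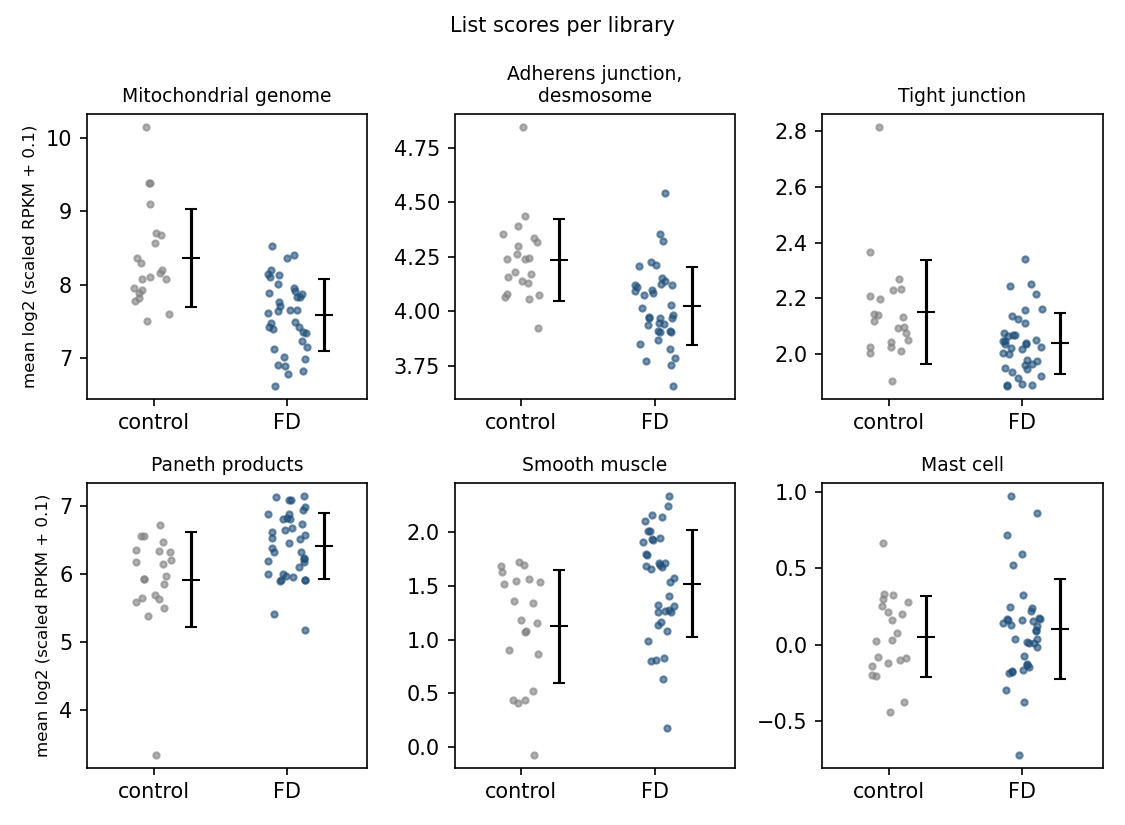
Mean log2 of scaled RPKM plus 0.1 over the members of 6 lists, 1 point per library, 21 controls (grey) and 37 functional dyspepsia libraries (FD, blue), with the mean and SD beside each group. The mitochondrial scores differ by -0.78, the tight junction scores by -0.11 (0.10 with the values as deposited) and the mast cell scores by 0.05, and the groups overlap in each panel.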

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

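Values as deposited, edgeR on recovered reads, pseudocounts, 5 surrogate variables and single-library fits were settings chosen after the data were seen. So were the shares of assigned, ribosomal and small nucleolar RNA reads, and list scores as deposited or with libraries left out. All other alternatives were fixed before. TMM scaling of RPKM in the main setting was itself kept only after the shift between groups had been seen. The plan for a unit other than counts named no rescaling. The counts of genes (2045 higher, 2738 lower) stayed within 1.5 times under RLE and upper-quartile scaling, other pseudocounts, no filter, edgeR, DESeq2, limma-voom, thinning to the smallest library and without the 3 most distant libraries. With the values as deposited they were 13776 and 370. Camera, in which a shift of all genes cancels, then called 5 lists higher and 20 lower, against 8 and 16 after scaling. The log2 fold changes of TGFB1 and NDUFS1 turned to 0.0431 and 0.0104. In that setting 14 list scores were higher and 1 lower. The direction turned for 16 of the 40 scores, 9 of them past the threshold in neither setting; the other 7 were tight junction (adjusted p = 0.109), adherens junction (0.888), ion transport (0.0716), cytokine (0.818), sensory and serotonin (0.0393), heat shock (0.909) and circadian genes (0.704). The median shift of all genes there shows the cause of the gene counts; for the settings below the cause was not tested unless fewer genes, libraries or a stricter threshold give it.

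A mean of at least 100 reads left 1254 genes higher (tight junction by camera 0.051). With 4 surrogate variables 4655 were higher and 4926 lower, with 5 of them 3808 and 4256. With the brush border score as a covariate 1490 were lower, camera called 3 lists higher and 9 lower, tight junction was lost (0.211), and lipid absorption (0.325), endothelium (0.755) and nuclear respiratory genes (0.369) turned. With the mitochondrial share camera called 1 list higher, and ribosomal protein (0.321) and histone genes (0.518) turned. This share also differed between the groups, so calls lost or gained with it cannot be told apart from removal of the group difference. With the library total 1235 genes were higher and 1023 lower, camera called 5 lists higher and 7 lower, tight junction was lost (0.1004) and nuclear respiratory genes turned (0.000493). Depth and group overlap, so this covariate removes part of both. Protein-coding genes alone gave 1167 and 1693 (tight junction 0.0837), an FDR of 0.01 gave 762 and 1425, and a fold over 1.5 by treat 5 and 11. The ribosomal RNA share left 3 lists higher; the small nucleolar RNA share left 1218 and 1709 genes and 4 lists higher. With an estimated correlation camera called 0 lists higher and 0 lower (tight junction and adherens junction adjusted p = 0.383), and fry called 2 higher and 13 lower, among them tight junction (0.0146) and adherens junction (0.001).

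Leaving out the libraries of 1 title prefix gave 974 to 2143 genes higher and 1264 to 2921 lower. Leaving out 1 library gave 1628 (without control replicate 8) to 2704 higher and 2307 to 3113 lower. Without the 3 most distant libraries the scores of cytokine (0.127), immediate-early (0.0696) and heat shock genes (0.0898) lost their calls. Among 5771 other values for genes and lists, 4857 kept direction and call, 709 lost the call, 190 gained it and 15 turned. No library had under 0.5 of the median total, so that setting gave no value.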

Other observations

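The tests on the junction and brush border lists, on the deposit of the controls, on mitochondrial transcripts and of depth for small nucleolar RNAs were chosen after the results, or related values in the same settings, were seen. SLC11A2, the apical iron importer, had a log2 fold change of -1.50 (SE 0.39, adjusted p = 0.00629) and -1.28 with the values as deposited. It lay below the control median in 26 of 37 functional dyspepsia libraries, short of the share the naming rule asks, and its call was lost with the library total as a covariate (-1.46, adjusted p = 0.063). CYBRD1 had a log2 fold change of -0.29 (adjusted p = 0.0316), lost with the values as deposited (adjusted p = 0.64) and without control replicate 3, 8, 10, 15, 16 or 17 (adjusted p up to 0.0576), and with the brush border score (-0.14, adjusted p = 0.353) or the library total (-0.21, adjusted p = 0.298) as a covariate. Both were chosen after their values were seen. CTSE fell by 0.64 (adjusted p = 0.000179) and CD68, a macrophage gene, fell by 0.50 (adjusted p = 4.16e-06), and both passed with the values as deposited. CD68 went against most of its list of 19 macrophage and dendritic cell genes, of which 14 had log2 fold changes above 0, 2 were higher and 2 lower (3 and 2 adjusted over the list alone), with a score difference of 0.07 (adjusted p = 0.467) that was 0.26 with the values as deposited (adjusted p = 0.0223). With the values as deposited 10 were higher and 1 lower, and with surrogate variables 5 and 2. By edgeR 0 were higher and 2 lower. By limma 0 were higher with the brush border score or the mitochondrial share as a covariate, where 3 and 0 were higher at an unadjusted p under 0.05. CD14 and CSF1R, the 2 higher on the scaled values, both lost their calls without control replicate 2, 9, 10 or 17. MRC1, chosen after its values were seen, passed without control replicate 10 or 17, and also in other fits that left out 1 library of either group. CD14 alone lost its call without control replicate 1, 12 or 21 and CSF1R alone without control replicate 6, 8, 13 or 18 (adjusted p up to 0.0793). Of 19 B and plasma cell genes 4 rose and 1 fell, over all genes and adjusted over the list alone, among them MZB1 and TNFRSF17, which rose by 0.54 and 0.49, and the score did not pass (difference 0.25, adjusted p = 0.0731; 0.45, adjusted p = 0.00671 with the values as deposited). It passed without control replicate 5 or 19 or functional dyspepsia replicate 11 or 35 (adjusted p = 0.035, 0.0213, 0.0455 and 0.0442). With the values as deposited 14 of these genes were higher, with surrogate variables 11, and by limma 0 with the brush border score, the mitochondrial share or the library total as a covariate, where 2, 2 and 4 were higher at an unadjusted p under 0.05. By edgeR 2 were higher. Without control replicate 19 the count of higher genes was 9, and the call of the lower gene was lost without control replicate 1, 2, 3, 4, 6, 7, 8, 16 or 19 or functional dyspepsia replicate 2, 6, 7, 13, 18, 19, 20, 21, 22, 24, 25, 27, 31, 32 or 34. Of 22 proliferation genes 6 rose over all genes and 8 adjusted over the list alone. The count of 6 was 19 with the values as deposited, 11 with surrogate variables, 2 without control replicate 6, 9, 12, 14 or 16 or functional dyspepsia replicate 3, 12, 15, 23, 25 or 33, 3 without control replicate 10, 15, 18, 19 or 20 or functional dyspepsia replicate 1, 5, 28, 32 or 35, 2 with a pseudocount of 1 or no filter, 3 with the library total as a covariate, and 1 with the brush border score or the mitochondrial share. Their score did not pass (adjusted p = 0.0731), and passed with the values as deposited (adjusted p = 0.000533) and without functional dyspepsia replicate 7 (adjusted p = 0.0466). The minor spliceosome RNA gene RNU6ATAC rose by 1.44 (SE 0.25), a call lost with the mitochondrial share as a covariate (0.67, adjusted p = 0.0551), and SCARNA3 rose by 1.03 (SE 0.12). TMEM107 rose by 0.87, but SNORD118 lies within its exons and was itself higher by 1.04.

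The number of genes called cannot be put down to an arbitrary split of the libraries: 1 of 100 splits, the real one, called as many genes (4783), and the highest of the others called 281. For lists called by camera the real split gave 24 and the highest other 23, again 1 of 100, so the preset correlation leaves little distance from chance. Within the controls the sets of libraries marked by title prefixes differed in 3 genes (highest other split 2) and within functional dyspepsia in 19 (highest other split 1), each with 1 of 100 splits as large, so a small structure follows the prefixes, whose meaning the labels do not give.

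Lower junction and brush border scores with higher smooth muscle scores may reflect less absorptive epithelium in the biopsies. Of 10 lists of other cell types 9 had higher scores, with differences from -0.08 for T cells, which include intraepithelial lymphocytes, to 0.40 for smooth muscle, and their spread passed a test against relabelled libraries with T cells (permutation p = 0.0319) and not without them (permutation p = 0.0755). A lower epithelial share therefore stays open, and with the brush border score as a covariate 2 of 34 tight junction genes were lower and 1 of 10 smooth muscle genes was higher. The spread test replaced a first comparison of the most extreme pair of lists, its version without T cells was added last, and the score test of scaling replaced camera, in which a shift of all genes cancels. Scaling stays open as a source. The adherens junction score was not lower with the values as deposited (adjusted p = 0.888). Leaving out the scale factors moved list scores up in general, adherens junction from -0.21 to 0.01 and mitochondrial from -0.78 to -0.56. That value therefore cannot test the junction genes in particular. The deposit of the controls cannot be told apart from the disease, as the groups share 0 title prefixes.

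Lower mitochondrial transcripts could come from less absorptive epithelium or from depth. With the brush border score as a covariate their median log2 fold change was -0.73, so that score alone does not account for it. With libraries thinned to the smallest it was -0.78. Random thinning keeps each gene's expected share of reads, so that value cannot test depth or a preparation difference that goes with it. With the library total as a covariate the median was -1.09, though depth and group overlap. The deposit of the controls, with 0 shared title prefixes, cannot be told apart from the disease, and RNA preparation could differ between deposits.

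Higher small nucleolar RNAs could come from depth or from retention of short fragments. After thinning 133 of these genes were higher, 121 of them among the 133 higher before it, so the calls did not rest on unequal numbers of reads. Thinning keeps each gene's expected share of reads, so it cannot test a library difference that goes with depth. Across 544 such genes the fold did not follow gene length (Spearman rho -0.0255, permutation p = 0.552, across genes, which are not independent replicates), so retention of short fragments stays open.

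A hypothesis was that functional dyspepsia biopsies were taken farther from the pylorus, which may raise Paneth products and lower iron transporters, so that these scores would be negatively related within each group. They were not detectably related in functional dyspepsia (r = -0.0344, permutation p = 0.839, rho = 0.0512, p = 0.764, n = 37; r = 0.141 without the 2 farthest libraries) or in controls (r = -0.0323, p = 0.889, rho = 0.188, p = 0.412, n = 21; r = 0.28 without them), with adjusted p of 0.889 for each r and 0.899 and 0.824 for rho over 6 relations computed. Paneth and gastric surface scores had rho = -0.483 in controls (permutation p = 0.0274, adjusted p = 0.164; r = -0.387, p = 0.0907, adjusted p = 0.544, and -0.456 without the 2 farthest libraries) and rho = 0.0301 in functional dyspepsia (p = 0.86; r = 0.0954, p = 0.576), and with Brunner gland scores rho was -0.275 (p = 0.227; r = -0.129, p = 0.65) and 0.0218 (p = 0.899; r = 0.0416, p = 0.806). The gastric surface score differed by -0.59 between groups (adjusted p = 0.0655; -0.39, adjusted p = 0.244 with the values as deposited), and passed without control replicate 11 or 15 or functional dyspepsia replicate 4 (adjusted p = 0.032, 0.0395 and 0.0243), with 1 of 7 genes lower by limma, over all genes and adjusted over the list alone, and 4 of these 7 by edgeR, or 6 of the 9 that its filter kept. With all libraries no relation and no score difference here passed after adjustment, and the hypothesis stays open, since the labels do not give the position of the biopsies.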
